A study of Arabidopsis thaliana with 18 samples.

How the data were processed

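PolyA RNA of whole 7-day-old seedlings was sequenced as paired-end 250 nt reads in 18 libraries: WT, ire1b and ire1a/ire1b (ire1a1b here), each with DMSO or 5 µg/mL TM for 6 h, in 3 replicates. Per the submitters' processing notes, the authors aligned the reads with STAR 2.4.0 to TAIR10 and counted them with HTSeq 0.6.0, and the deposited files held raw counts per gene, in which every value was a whole number. The counting mode, the strand setting and the annotation version were not given in the sources used here, so counts of antisense or overlapping genes and of near-identical copies were uncertain. DESeq2 was named in those notes without a version, and none of its results were used. The HTSeq summary entries (no feature 1.202% to 1.419%, ambiguous 1.094% to 1.231%, not unique 3.331% to 3.713% of all counts) were left out. Replicates were numbered by the sample titles, since the replicate tag inside the labels conflicted with them. The sources said nothing of separate cultures, so the p-values measure the spread between these samples, which may be technical.

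Each file listed 27416 identifiers, of which 26719 matched a locus of the TAIR10.1 reference annotation, 697 did not and 10376 had a gene symbol. Coordinates are those of TAIR10.1. Totals ranged from 16.35 to 24.85 M gene counts per library, the 10 most abundant genes held 3.737% to 4.538%, and chi-square per degree of freedom between replicates ranged from 2.725 to 57.59, so the spread between replicates was above counting noise. Genes were kept by filterByExpr with the 6 groups (20615 kept, 6801 not), scaled by TMM (factors 0.9473 to 1.066) and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with 1 mean per group over all 18 libraries. There were 9 comparisons: TM against DMSO in each genotype, the 3 interactions between these responses, and the 3 genotype differences in DMSO. P-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison, and genes with adjusted p below 0.05 were called. All adjusted p-values are from these fits unless another tool is named. Log2 fold changes are given with their SE, and CPM values (TMM-scaled) as mean ± SD of 3 libraries unless n is given.

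The comparisons, the main test, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule took IRE1A, IRE1B, BZIP60, BIP3 and NAC103 in every TM comparison. It also took the 10 largest changes per direction in each TM response and the 8 largest per direction in each DMSO comparison. From each interaction with WT it took the 8 smallest p-values per direction (5 in ire1a1b against ire1b). The ranked genes were taken among called genes with a mean log2 CPM of at least 2. Outside the interactions, the CPM values of the 2 groups also had to be without overlap. Any member of a gene list could be named as an example. The 21 lists were ER folding, ER-associated degradation, UPR regulators, ER translocation and N-glycosylation, autophagy, ER body and associated lectins, salicylate and camalexin defence, jasmonate, cytosolic heat shock, hypoxia, mitochondrial retrograde response, mitotic cell cycle, photosynthesis (green shoot markers), root hair and root endodermis (root markers), expansins, xyloglucan endotransglucosylase/hydrolases, arabinogalactan and fasciclin-like proteins, class III peroxidases, lipid transfer proteins and cytosolic ribosomal proteins. The list of ER translocation and N-glycosylation also held SARA1A (AT1G09180) and AT1G18830, entered there as SAR1A and SEC31A. ATG14A and ATG14B were dropped from autophagy on a name mismatch. From the ribosomal list 50 pattern matches were dropped because their product name did not mark them as cytosolic. RPL5B, RPL18 and RPS13A were among these, so the 11 genes kept (8 tested) may not stand for the family. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 21 lists of a comparison, with the correlation estimated from the residuals given beside it and fry as an alternative.

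Replicates were treated as unpaired. The correlation of gene residuals between libraries of equal replicate number was 0.5 to 0.69 for TM in WT, 0.15 to 0.32 in ire1b, 0.42 to 0.72 in ire1a1b, 0.34 to 0.84 for the interaction of ire1a1b with WT and 0.58 to 0.84 for ire1a1b against WT in DMSO, all at or above the threshold of 0.1 used for pairing. The lowest values of the other 4 comparisons were 0.01 to 0.07, below it. A replicate block was therefore run as an alternative for every comparison. The others were RLE scaling, DESeq2 1.42.0, no filter, a filter of at least 1 CPM in 3 libraries, a size threshold of log2 1, fits to the groups of a comparison alone, thinning to the smallest library and each library left out in turn. Added after the data were seen were a fit without the 4 replicate 1 libraries of WT and ire1a1b, 1 without replicate 1 of every group and 1 with a block within each genotype, and also the left-out libraries for lists and for the overlap and RLE scaling for the overlap, and fits to the groups of a comparison alone for named genes. Other splits of the samples were counted in all 10 ways for 3 against 3 and in 100 ways for the interactions.

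The pipeline was tested on simulated data with 200 of 20615 genes changed. At 2-fold and 4-fold it recovered 149 and 188 for TM in WT (8 and 10 false calls), 116 and 173 for the interaction of ire1a1b with WT (9 and 12) and 158 and 186 for ire1a1b against WT in DMSO (9 and 8). Besides the 200, the class III peroxidases were lowered in the changed group and left out of the false calls. Simulated libraries were drawn independently, without the shared spread by replicate number, so these counts do not cover that structure. For the protein scan, the coding sequences of 27367 genes were translated, and an N-terminal hydrophobic segment was counted where a window of 11 residues within the first 40 had a mean hydropathy of at least 2.0. This segment stands in for a signal peptide or a membrane anchor and does not tell them apart. Spliced BZIP60 mRNA could not be measured from gene counts.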

Results

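The series held 18 libraries of 7-day-old Arabidopsis seedlings in 6 groups of 3. The labels named WT, ire1b and ire1a/ire1b (written ire1a1b here), each given DMSO or 5 µg/mL tunicamycin (TM), which blocks N-glycosylation, for 6 h. Total gene counts ranged from 16.35 to 24.85 M per library, and 20615 of 27416 genes were tested. The first 3 principal components held 41.6%, 20.7% and 13.2% of the variance. The 4 replicate 1 libraries of WT and ire1a1b stood apart on component 2, at 31 to 47.5, against -19.2 to 3.5 for replicates 2 and 3 of these genotypes and -27.1 to -1.5 for the libraries labelled ire1b.

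The first question was whether IRE1A and IRE1B, which encode ER stress sensors with kinase and ribonuclease domains, were lowered in the libraries labelled as mutants. IRE1A (AT2G17520, chromosome 2, 7617151 to 7621129, TAIR10.1) stood at 85.3 ± 5.67 CPM in WT (mean ± SD over 6 libraries, range 79.7 to 93.1). It stood at 96.5 ± 5.01 in the libraries labelled ire1b (89.2 to 103) and at 23 ± 1.73 in those labelled ire1a1b (19.9 to 24.7). In DMSO it was 4.02-fold lower in ire1a1b than in WT (log2 -2.01 ± 0.07 SE, n = 3 per group, adjusted p = 4.7e-10). It was 4.23-fold lower than in ire1b (log2 -2.08 ± 0.07, adjusted p = 2.9e-10). IRE1B (AT5G24360, chromosome 5, 8316388 to 8319981) was not lower in either label. It stood at 33.3 ± 3.38 CPM in WT (28 to 36.7), 39.6 ± 4.06 in the libraries labelled ire1b (35.5 to 47.2) and 39.3 ± 4.29 in those labelled ire1a1b (35.5 to 47.4). The DMSO log2 differences of IRE1B were 0.36 ± 0.11 (ire1b against WT, adjusted p = 0.88), 0.23 ± 0.11 (ire1a1b against WT, adjusted p = 1) and -0.13 ± 0.11 (ire1a1b against ire1b, adjusted p = 0.93). Gene counts backed the ire1a part of the label ire1a1b and did not show the ire1b part of either label. Every direction below is therefore drawn between libraries labelled ire1b or ire1a1b and WT.

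**Figure D1:**
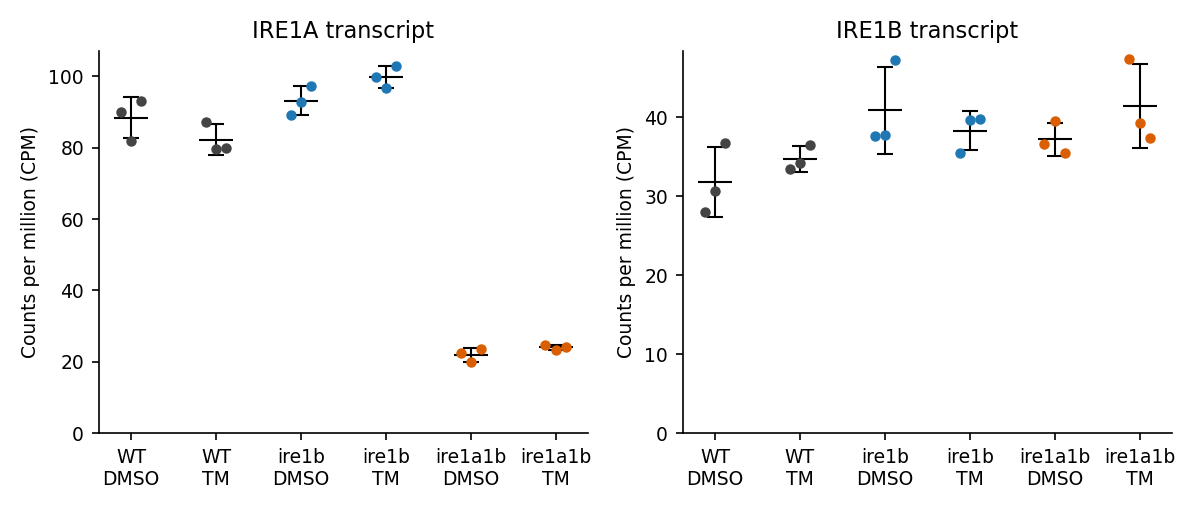
CPM of IRE1A and IRE1B in each of the 18 libraries, by labelled group, with the mean and SD of 3 libraries.

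The next question was which transcripts TM changed in WT. BIP3 (AT1G09080, chromosome 1, 2929217 to 2931850), an ER HSP70 chaperone, went from 2.63 ± 0.934 to 2890 ± 155 CPM, a 1090-fold rise (log2 10.09 ± 0.37, adjusted p = 1.6e-11, n = 3). NAC103 (AT5G64060, chromosome 5, 25633455 to 25635789), a transcription factor gene, rose 67.8-fold to 138 ± 22.7 CPM (log2 6.08 ± 0.15, adjusted p = 1.6e-13). TIN1 (AT5G64510) rose 118-fold (log2 6.89 ± 0.29, adjusted p = 7.9e-11). AT3G15980 (chromosome 3, 5411278 to 5418632), annotated as a coatomer beta' subunit, rose 16.7-fold to 2120 ± 269 CPM (log2 4.06 ± 0.1, adjusted p = 1.6e-13). SARA1A (AT1G09180), a small GTPase of the SAR1 type, had 9 counts over the 3 DMSO libraries and 5824 over the 3 TM libraries. AT1G18830, a WD40 repeat gene, had 75 and 28466. AT3G55700, a UDP-glycosyltransferase gene, rose 48.7-fold (log2 5.61 ± 0.2, adjusted p = 1.1e-11). AT3G60540, a Sec61 beta subunit gene, rose 21.1-fold (log2 4.4 ± 0.17, adjusted p = 2.4e-11).

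Of 22 ER folding genes tested in WT, 19 rose, 2 fell and 1 did not pass (19 and 2 adjusted over the list alone, median log2 3.35, camera adjusted p = 7.5e-08 with an estimated correlation). Those that rose included BIP2 (AT5G42020), at 326 ± 46 and 5500 ± 379 CPM (16.9-fold, log2 4.08 ± 0.13, adjusted p = 2.8e-12), and the ER J-domain gene ERDJ3A (AT3G08970, 42-fold, log2 5.39 ± 0.24, adjusted p = 2.1e-10). Others were calnexin CNX1 (AT5G61790, 12.3-fold, log2 3.61 ± 0.1, adjusted p = 6.6e-13) and HSP90.7 (AT4G24190, 12.1-fold, log2 3.6 ± 0.09, adjusted p = 3e-13). Of 11 ER-associated degradation genes 9 rose and 2 did not pass (9 over the list alone, median 1.99, camera adjusted p = 1.4e-92, 6.8e-08 with an estimated correlation). HRD1B (AT1G65040) rose 12.3-fold (log2 3.62), DER1 (AT4G29330) 5.87-fold (log2 2.55 ± 0.07) and UBC32 (AT3G17000) 3.82-fold (log2 1.93 ± 0.07). Of 15 genes of ER translocation and N-glycosylation 12 rose and 3 did not pass (14 over the list alone, median 1.54, camera adjusted p = 1e-93, 6.8e-08 with an estimated correlation). The Sec61 alpha gene AT1G29310 rose 7.86-fold (log2 2.97). Of 13 regulators of the unfolded protein response (UPR) 7 rose and 6 did not pass (7 over the list alone, median 0.28, camera adjusted p = 1.5e-18, 0.00056 with an estimated correlation). BZIP60 (AT1G42990), whose mRNA is spliced by IRE1, rose 2.6-fold (log2 1.38 ± 0.28, adjusted p = 0.0046). NAC089 (AT5G22290) rose 8.5-fold (log2 3.09 ± 0.15, adjusted p = 5.7e-10) and BI1 (AT5G47120) rose 6.08-fold (log2 2.6 ± 0.21, adjusted p = 3.1e-07). UTR1 (AT2G02810), an ER nucleotide sugar transporter, rose 14.5-fold (log2 3.85 ± 0.14, adjusted p = 1e-11).

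Among the genes that fell most in WT, BGLU21 (AT1G66270), a beta-glucosidase, fell 8.66-fold from 212 ± 16.5 to 24.5 ± 4.33 CPM (log2 -3.11 ± 0.15, adjusted p = 5e-10). XTH26 (AT4G28850) fell 7.77-fold (log2 -2.96 ± 0.16, adjusted p = 1.4e-09). The others with the largest falls were VSP1 (AT5G24780, log2 -3.04 ± 0.44), XTH13 (AT5G57540, -2.91 ± 0.23), the chitinase gene AT2G43620 (-2.8 ± 0.4), the lipase gene GLL22 (AT1G54000, -2.51 ± 0.18) and the papain family protease gene AT4G11320 (-2.39 ± 0.23). They also held the peroxidase genes AT2G38390 (-2.49 ± 0.17), PRXCB (AT3G49120, -2.43 ± 0.16) and AT2G39040 (-2.35 ± 0.19). Of 59 class III peroxidases 34 fell and 25 did not pass (40 fell and 1 rose over the list alone, median log2 -0.84, camera adjusted p = 1.4e-22, 0.00056 with an estimated correlation). Of 27 xyloglucan endotransglucosylase/hydrolases 10 fell and 17 did not pass (12 over the list alone, median -0.59, camera adjusted p = 2.6e-10, 0.0014 with an estimated correlation). Of 43 arabinogalactan and fasciclin-like genes 16 fell and 27 did not pass (20, median -0.44, 7.3e-10, 0.011 with an estimated correlation). Of 19 ER body and lectin genes 7 fell and 12 did not pass (9 over the list alone, median -0.46, camera adjusted p = 7.6e-12, 0.043 with an estimated correlation). BGLU23 (PYK10, AT3G09260) fell 3.27-fold (log2 -1.71 ± 0.18, adjusted p = 6.3e-06). Of 19 expansins 5 fell and 14 did not pass (8 over the list alone, median -0.38, camera adjusted p = 0.0011, and adjusted p = 0.063 with an estimated correlation). Of 6 lipid transfer proteins 4 fell and 2 did not pass (4, median -0.49, 0.0044 and adjusted p = 0.043 with an estimated correlation).

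Root tissue markers moved with these falls in WT. Of 6 root hair markers 4 fell and 2 did not pass (4 over the list alone, median log2 -0.83, camera adjusted p = 5e-05, 0.02 with an estimated correlation). Of 8 endodermis markers 5 fell, CASP4 (AT5G06200) by 6.23-fold, and 3 did not pass (7 over the list alone, median -0.78, 5e-05, 0.04 with an estimated correlation). Of 40 autophagy genes 3 rose and 37 did not pass (3 over the list alone, median 0.09, camera adjusted p = 0.25). NBR1 (AT4G24690), a selective autophagy receptor gene, stood at 496 ± 90.5 CPM in DMSO and 579 ± 86.1 with TM (log2 0.22 ± 0.15, adjusted p = 0.41). The remaining lists gave no call in WT. These were salicylate and camalexin defence (1 of 14 rose, median -0.29, camera adjusted p = 0.56), jasmonate (2 of 12 fell, -0.18, 0.16) and photosynthesis (1 of 19 rose, -0.14, 0.56). They also held cytosolic ribosomal proteins (8 of 8 not passing, -0.03, 0.56), mitotic cell cycle (10 of 10 not passing, -0.18, 0.37), cytosolic heat shock (8 of 8 not passing, -0.03, 0.99) and hypoxia (11 of 11 not passing, -0.03, 0.99). The 5 genes of the mitochondrial retrograde response did not pass, with a median of -0.03 and a mean of -0.01 while the test pointed up (adjusted p = 0.84).

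Over all genes, 1264 rose and 1189 fell with TM in WT, 2453 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). A fit to the WT libraries alone gave 848. A replicate block gave 4142 (5811 within each genotype), and the count was 1553 without the second and 1606 without the third WT TM library.

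The same question was asked of the libraries labelled ire1b. TM raised BIP3 246-fold to 2810 ± 161 CPM there (log2 7.94 ± 0.34, adjusted p = 7.6e-11). NAC103 rose 79.8-fold to 130 ± 10.2 CPM (log2 6.32 ± 0.15, adjusted p = 1.7e-13). BIP2 rose 16.7-fold (log2 4.06 ± 0.13, adjusted p = 2.7e-12). HSP90.7 rose by log2 3.59 ± 0.09, TIN1 by 6.03 ± 0.27, ERDJ3A by 5.59 ± 0.24, AT3G55700 by 4.89 ± 0.19 and BZIP60 by 1.66 ± 0.28 (adjusted p = 0.00052). SARA1A had 40 counts in DMSO and 6411 with TM, and AT1G18830 had 143 and 21439. AATP1 (AT5G40010), an AAA ATPase gene, rose 43.9-fold from 1.94 ± 0.35 to 84.5 ± 10.1 CPM (log2 5.46 ± 0.21, adjusted p = 2.7e-11). BGLU25 (AT3G03640) rose 40.3-fold to 2070 ± 25.5 CPM (log2 5.33 ± 0.2, adjusted p = 2.1e-11). ETC1 (AT1G01380), a MYB-related gene, rose 26-fold (log2 4.7 ± 0.19). The largest falls were of AT1G19900, a glyoxal oxidase-related gene (log2 -5.15 ± 0.33, 35.6-fold), XTH26 (-4.66 ± 0.18, 25.2-fold), AGP30 (AT2G33790, -4.21 ± 0.3), AT2G39040 (-4.12 ± 0.23) and XTH13 (-3.52 ± 0.24). Next came PRP1 (AT1G54970, -3.4 ± 0.26), the pectin methylesterase inhibitor genes AT5G04960 (-3.34 ± 0.15) and AT5G62340 (-2.89 ± 0.21), the potassium channel gene SKOR (AT3G02850, -3.3 ± 0.32) and the peroxidase gene AT1G34510 (-2.93 ± 0.21).

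In the libraries labelled ire1b 19 of 22 ER folding genes rose and 1 fell (19 and 1 over the list alone, median log2 3.43, camera adjusted p = 1.2e-06 with an estimated correlation). ER-associated degradation genes rose in 9 of 11 (9, median 2.08, 1.2e-06 with an estimated correlation). Those of ER translocation and N-glycosylation rose in 10 of 15 (11 rose and 1 fell over the list alone, median 1.58, 1.1e-06 with an estimated correlation). UPR regulators rose in 6 of 13 (8, median 0.24, 0.0028 with an estimated correlation), BZIP28 (AT3G10800) by 2.5-fold (log2 1.32 ± 0.12, adjusted p = 7.4e-07). Of 40 autophagy genes 9 rose (9 over the list alone, median 0.13, camera adjusted p = 0.0044, but adjusted p = 0.25 with an estimated correlation). NBR1 rose 3.44-fold to 1740 ± 147 CPM (log2 1.78 ± 0.15, adjusted p = 4.1e-07). ATG8D (AT2G05630) rose 3.69-fold (log2 1.88 ± 0.08, adjusted p = 4.9e-11) and ATG13B (AT3G18770) rose 2.73-fold (log2 1.45 ± 0.13, adjusted p = 5.2e-07). Of the ER body and lectin genes 14 of 19 fell (14, median -1.03, camera adjusted p = 3.8e-13, 0.04 with an estimated correlation). JAL34 (AT3G16460) fell 2.75-fold and NAI1 (AT2G22770), a regulator of ER body formation, 2.04-fold. Of 59 class III peroxidases 33 fell and 2 rose (38 and 3, median -0.83, 3.4e-15, 0.0028 with an estimated correlation). Of 27 xyloglucan endotransglucosylase/hydrolases 7 fell and 2 rose (8 and 2, median -0.28, 2e-05, 0.02 with an estimated correlation). Of 19 expansins 9 fell and 1 rose (10 and 1, median -0.43, 2e-04, 0.046 with an estimated correlation), and EXPA7 (AT1G12560) fell 3.1-fold. All 6 root hair markers fell (6, median -1.36, 3.1e-08, 0.0041 with an estimated correlation). So did 5 of 8 endodermis markers (6, median -1.45, 0.00014, 0.048 with an estimated correlation). Over all genes 2252 rose and 2387 fell, 4639 in all (edgeR quasi-likelihood), and 7861 with a replicate block within each genotype.

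Then came the TM response of the libraries labelled ire1a1b. NAC103 stood at 1.49 ± 0.259 CPM in DMSO and 1.94 ± 0.227 with TM (log2 0.35 ± 0.18, adjusted p = 0.25). AT3G15980 stood at 110 ± 4.97 and 128 ± 3.8 CPM (log2 0.21 ± 0.09, adjusted p = 0.12). SARA1A had 13 counts and 23, and AT1G18830 had 2 and 5. BIP3 still rose 79.4-fold, to 102 ± 6.22 CPM (log2 6.31 ± 0.34, adjusted p = 2.7e-09). BIP2 rose 11.5-fold to 4220 ± 134 CPM (log2 3.52 ± 0.13, adjusted p = 2.2e-11). BZIP60 did not pass (136 ± 54.3 and 231 ± 23.7 CPM, log2 0.76 ± 0.28, adjusted p = 0.085). It passed with DESeq2 (0.044), with a replicate block (0.01) and without the 4 replicate 1 libraries of WT and ire1a1b (0.0011). AATP1 rose 48-fold to 73.2 ± 12 CPM (log2 5.59 ± 0.21, adjusted p = 5e-11). BGLU25 rose 34.5-fold to 1560 ± 131 CPM (log2 5.11 ± 0.2, adjusted p = 6.5e-11). Other large rises were of ERDJ3A (log2 4.44 ± 0.23), TIN1 (4.37 ± 0.26), CNGC19 (AT3G17690, 4.36 ± 0.21) and SNRK2-8 (AT1G78290, 4.1 ± 0.45). So were those of AT1G52855 (3.96 ± 0.41), GSTU22 (AT1G78340, 3.94 ± 0.38) and AT3G48770 (3.84 ± 0.27). The largest falls were of AT1G19900 (-5.35 ± 0.35), AT2G39040 (-4.36 ± 0.24), AGP30 (-4.22 ± 0.31), XTH26 (-4.21 ± 0.18) and AT5G04960 (-3.4 ± 0.16). Next came XTH13 (-3.27 ± 0.23), AT5G60520 (-3.25 ± 0.24), AT5G62340 (-3.08 ± 0.21), GASA5 (AT3G02885, -2.99 ± 0.29) and PRP1 (-2.84 ± 0.25).

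In the libraries labelled ire1a1b 19 of 22 ER folding genes rose and 3 did not pass (19 over the list alone, median log2 2.68, camera adjusted p = 1.3e-06 with an estimated correlation). Of the ER-associated degradation genes 7 of 11 rose (7, median 1.5, 1.1e-05 with an estimated correlation), UBC32 by 1.65-fold (log2 0.73 ± 0.07, adjusted p = 9.6e-07). Of the UPR regulators 4 of 13 rose (5, median 0.16, 0.033 with an estimated correlation), NAC089 by 2.66-fold and BZIP28 by 2.69-fold. Of the genes of ER translocation and N-glycosylation 8 of 15 rose and 1 fell (9 and 1, median 1.05, 1.1e-05 with an estimated correlation). Of 8 cytosolic heat shock genes 6 rose (7 over the list alone, median 1.75, camera adjusted p = 3.8e-05, but adjusted p = 0.18 with an estimated correlation). HSP70 (AT3G12580) rose by 3.65-fold (log2 1.87 ± 0.4, adjusted p = 0.0043) and HSP90.1 (AT5G52640) by 3.38-fold (log2 1.76 ± 0.38, adjusted p = 0.0047). Of 40 autophagy genes 10 rose (11 over the list alone, median 0.14, 9.9e-05, but adjusted p = 0.1 with an estimated correlation), NBR1 by 3.7-fold to 1720 ± 52.5 CPM and ATG8D by 3.51-fold. Of 59 class III peroxidases 21 fell and 3 rose (24 and 3, median -0.33, 5.2e-09, 0.019 with an estimated correlation). Of 19 ER body and lectin genes 13 fell (14, median -0.75, 2.6e-10, but adjusted p = 0.067 with an estimated correlation). Of 19 expansins 8 fell and 1 rose (10 and 2, median -0.53, 1.3e-05, 0.025 with an estimated correlation). Of 27 xyloglucan endotransglucosylase/hydrolases 6 fell and 2 rose (7 and 3, median -0.15, 9.9e-05, 0.032 with an estimated correlation). The arabinogalactan and fasciclin-like genes (5 rose and 8 fell of 43) had a median of 0.06 and a mean of -0.14, and the test pointed down (camera adjusted p = 0.28). The root hair markers fell in 5 of 6 (6 over the list alone, median -1.19, 7.9e-11, 0.0015 with an estimated correlation). The endodermis markers fell in 5 of 8 (7, median -1.54, 2.7e-08, 0.013 with an estimated correlation), CASP4 by 10.5-fold. Over all genes 1705 rose and 1359 fell, 3064 in all (edgeR quasi-likelihood), 1567 in a fit to the ire1a1b libraries alone, and 4844 with a replicate block (6337 within each genotype).

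**Figure D2:**
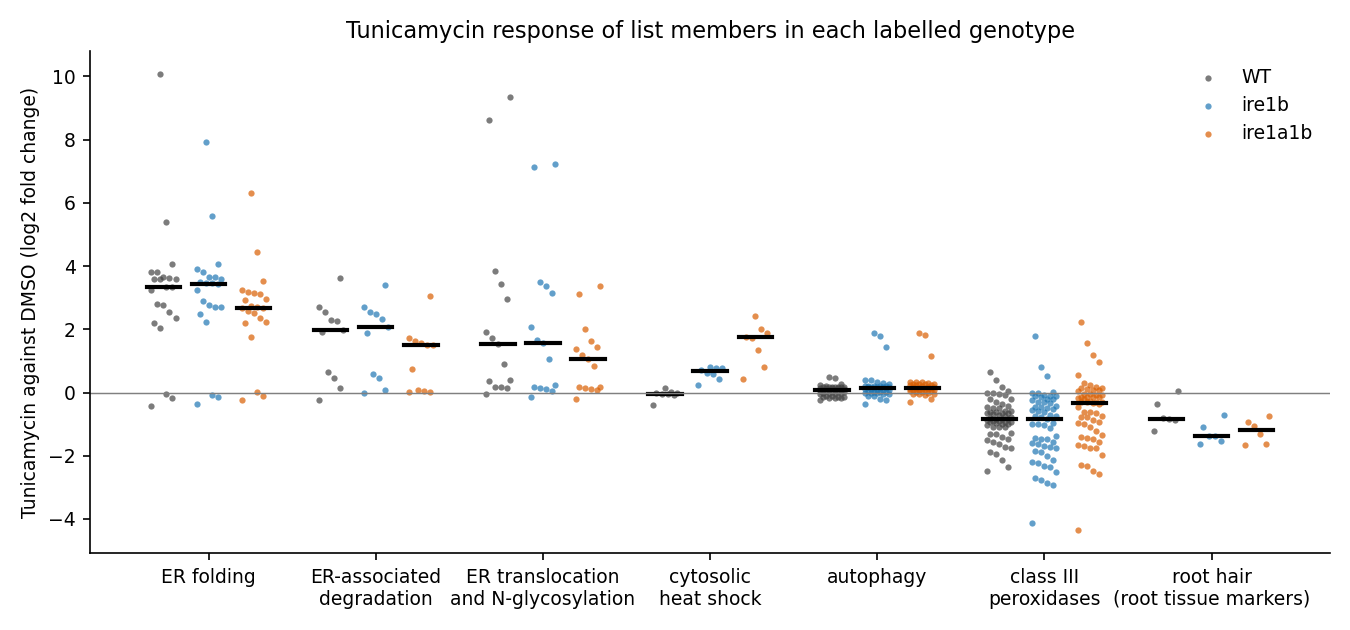
TM response (log2 fold change) of the members of 7 gene lists in WT and in the libraries labelled ire1b and ire1a1b. The black line is the median.

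The overlap of the TM responses was counted next. In all 3 genotypes 490 genes rose, against 11.4 under independence, and 429 fell, against 9.08. WT and the libraries labelled ire1b shared 881 rises and 748 falls. WT and those labelled ire1a1b shared 502 and 452, and the libraries of both mutant labels shared 1307 and 1108. Across the tested genes the log2 fold changes had a correlation of 0.7 between WT and ire1b, 0.51 between WT and ire1a1b and 0.82 between ire1b and ire1a1b.

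The interaction term then tested where the TM response of the libraries labelled ire1b differed from WT. The callose synthase genes GSL04 (AT3G14570) and GSL11 (AT3G59100) were among the clearest. GSL04 stood at 26 ± 0.743 and 29 ± 2.8 CPM in WT and at 25.2 ± 0.117 and 167 ± 10.1 in ire1b, a response 5.93-fold larger (log2 2.57 ± 0.13, adjusted p = 5.4e-08). That of GSL11 was 4.43-fold larger (log2 2.15 ± 0.15, adjusted p = 1e-06). The response was also larger for BGLU25 (11.3-fold, log2 3.49 ± 0.25, adjusted p = 1.2e-06), AATP1 (16-fold, log2 4 ± 0.34, adjusted p = 5e-06) and KOB1 (AT3G08550, 2.76-fold). It was larger for NBR1 (2.94-fold, log2 1.56 ± 0.21, adjusted p = 0.00032), ATG8D (2.6-fold, log2 1.38 ± 0.11, adjusted p = 2.7e-06) and BZIP28 (log2 0.87 ± 0.17, adjusted p = 0.006). It was lower for the acyltransferase gene AT4G15390, at 81.4 ± 14 and 88.9 ± 7.58 CPM in WT and 78.7 ± 8.26 and 13.4 ± 0.572 in ire1b (log2 -2.68 ± 0.25, adjusted p = 8.1e-06). It was also lower for the ammonium transporter gene AMT1;3 (AT3G24300, -2.4 ± 0.24, adjusted p = 1.7e-05) and for BIP3 (-2.15 ± 0.39, adjusted p = 0.0036). The BIP3 difference rested on DMSO, where it stood at 11.3 CPM in ire1b and 2.63 in WT, since its TM values overlapped. That DMSO call was lost when single libraries were left out (below). NAC103 (log2 0.24 ± 0.21, adjusted p = 0.79), BZIP60 (0.28, adjusted p = 0.91) and BIP2 (-0.01, adjusted p = 1) did not pass. BZIP60 passed without the 4 replicate 1 libraries (0.46, adjusted p = 0.038).

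By list, the ire1b against WT difference had no call for ER folding (1 of 22 below, median 0.07 and mean -0.03 of opposite sign, camera adjusted p = 0.69) or ER-associated degradation (11 of 11 not passing, adjusted p = 0.97). The 5 list calls were all lost with an estimated correlation. For arabinogalactan and fasciclin-like genes 5 responses were higher and 2 lower (7 and 2 over the list alone, median 0.35, camera adjusted p = 0.001, but adjusted p = 0.3 with an estimated correlation). AGP18 (AT4G37450) stood at log2 1.69 ± 0.23 (adjusted p = 0.00032) and FLA12 (AT5G60490) at 1.88 (adjusted p = 0.00032). For root hair markers 2 were lower (4 over the list alone, median -0.59, 0.001, but adjusted p = 0.26 with an estimated correlation). For autophagy 3 were higher (3, median 0.06, 0.018, but adjusted p = 0.71 with an estimated correlation, and 0.061 without the second ire1b DMSO library). For ER body and lectin genes 1 was higher and 3 lower (1 and 7, median -0.29, 0.024, but adjusted p = 0.77 with an estimated correlation). That call ended at 0.052 without WT DMSO replicate 3, 0.15 without WT TM replicate 1, 0.076 without ire1b DMSO replicate 2 and 0.27 without ire1b TM replicate 3. For lipid transfer proteins 6 of 6 did not pass (1 higher over the list alone, median 0.55, 0.043, but adjusted p = 0.3 with an estimated correlation). It ended at 0.084 without WT DMSO replicate 1, 0.08 without WT DMSO replicate 2, 0.084 without WT TM replicate 3, 0.097 without ire1b DMSO replicate 3 and 0.11 without ire1b TM replicate 2. Over all genes 525 responses were higher and 330 lower in the libraries labelled ire1b, 855 in all (edgeR quasi-likelihood), 1567 with a replicate block (2467 within each genotype) and 1295 without the 4 replicate 1 libraries of WT and ire1a1b. Of the 525, 319 rose in ire1b with no call in WT, and of the 330, 230 fell in ire1b with no call in WT.

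The interaction of the libraries labelled ire1a1b with WT asked which responses were lost or gained there. The coatomer beta' gene AT3G15980 responded 14.4-fold less (log2 -3.84 ± 0.13, adjusted p = 1.1e-10) and the coatomer alpha gene AT1G62020 4.26-fold less (-2.09 ± 0.11, adjusted p = 1.8e-08). ARFA1D (AT1G70490), a small GTPase gene, stood at 2560 ± 272 CPM with TM in WT and 371 ± 7.77 in ire1a1b, a 6.25-fold smaller response (-2.64 ± 0.14, adjusted p = 1.8e-08). NAC103 was 53-fold lower in its response (-5.73 ± 0.23, adjusted p = 1.2e-09) and BIP3 13.7-fold (-3.78 ± 0.46, adjusted p = 8e-05). The response of SVB (AT1G56580) was lower 6.74-fold (-2.75 ± 0.12, adjusted p = 2.7e-09) and that of TIN1 5.72-fold (-2.52 ± 0.35, adjusted p = 0.00027). SARA1A (log2 -8.53 ± 0.84, adjusted p = 1e-05) rested on near-zero counts. AT1G18830 did not pass (-7.42 ± 2.38, adjusted p = 0.089), which also rested on near-zero counts. It had 75 counts in DMSO and 28466 with TM in WT, against 2 and 5 in ire1a1b. The missing call therefore does not show a like response. BIP2 (-0.56, adjusted p = 0.058) and BZIP60 (-0.62 ± 0.39, adjusted p = 0.51) did not pass. BZIP60 passed without the 4 replicate 1 libraries (-0.66, adjusted p = 0.0062). Responses were larger than in WT for BGLU25 (log2 3.27 ± 0.25, adjusted p = 7.8e-07) and AATP1 (4.13 ± 0.35, adjusted p = 2.1e-06). So they were for the callose synthase genes GSL04 (2.65 ± 0.13, adjusted p = 6.8e-09), GSL11 (2.2 ± 0.15), GSL8 (AT2G36850, 1.44 ± 0.1) and GSL10 (AT3G07160, 1.14 ± 0.08). BGLU21 fell 8.66-fold in WT and 3.01-fold in ire1a1b (difference 1.52 ± 0.2, adjusted p = 0.00016). PRXCB fell 5.37-fold in WT and did not pass in ire1a1b (231 ± 44.6 and 176 ± 14.7 CPM, difference 2.03 ± 0.22, adjusted p = 2.5e-05).

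Of the ER-associated degradation genes 9 of 11 responded less in the libraries labelled ire1a1b than in WT (9 over the list alone, median log2 -0.58, camera adjusted p = 1.1e-15, 0.0013 with an estimated correlation). UBC32 differed by -1.21 ± 0.09 (adjusted p = 8.5e-07) and DER1 by -1.04 ± 0.09 (adjusted p = 3.7e-06). Of the ER folding genes 8 of 22 responded less and 1 more (13 and 2, median -0.41, 1.8e-11, but adjusted p = 0.12 with an estimated correlation). HSP90.7 stood at -0.92 ± 0.12 (adjusted p = 0.00016), PDIL2-3 (AT2G32920) at -1.48 ± 0.08 (adjusted p = 3.6e-08) and ERO1 (AT1G72280) at -1.29 ± 0.2 (adjusted p = 0.00092). Of the UPR regulators 3 of 13 responded less and 1 more (3 and 1 over the list alone, median -0.06, 0.00013, but adjusted p = 0.12 with an estimated correlation). NAC089 differed by -1.67 ± 0.2 (adjusted p = 8.2e-05), and BZIP28 was the 1 that responded more (0.98 ± 0.17, adjusted p = 0.0018). For ER translocation and N-glycosylation 3 of 15 were lower (7, median -0.3, 2.5e-05, but adjusted p = 0.062 with an estimated correlation). For autophagy 4 of 40 were higher (4, median 0.11, 0.006, but adjusted p = 0.28 with an estimated correlation). NBR1 differed by 1.66 ± 0.21 (adjusted p = 0.00013) and ATG8D by 1.31 ± 0.11 (adjusted p = 1.8e-06). For cytosolic heat shock 2 of 8 were higher (6, median 1.8, 6.7e-06, but adjusted p = 0.16 with an estimated correlation), HSP101 (AT1G74310) by 1.3 ± 0.28. For class III peroxidases 12 of 59 were higher and 3 lower (18 and 12, median 0.38, 0.00073, but adjusted p = 0.16 with an estimated correlation). For arabinogalactan and fasciclin-like genes 8 of 43 were higher and 2 lower (15 and 2, median 0.47, 3e-06, but adjusted p = 0.095 with an estimated correlation). For lipid transfer proteins 1 of 6 was higher (2, median 0.49, 0.02, but adjusted p = 0.12 with an estimated correlation). For root hair markers 1 of 6 was lower (2, median -0.52, 0.0053, but adjusted p = 0.12 with an estimated correlation, and 0.066 without the 4 replicate 1 libraries). Over all genes 762 responses were higher and 500 lower, 1262 in all (edgeR quasi-likelihood), and 2341 with a replicate block (3486 within each genotype). Of the 762, 416 rose in ire1a1b with no call in WT and 163 fell in WT with no call in ire1a1b. Of the 500, 174 rose in WT with no call in ire1a1b and 170 fell in ire1a1b with no call in WT.

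**Figure D3:**
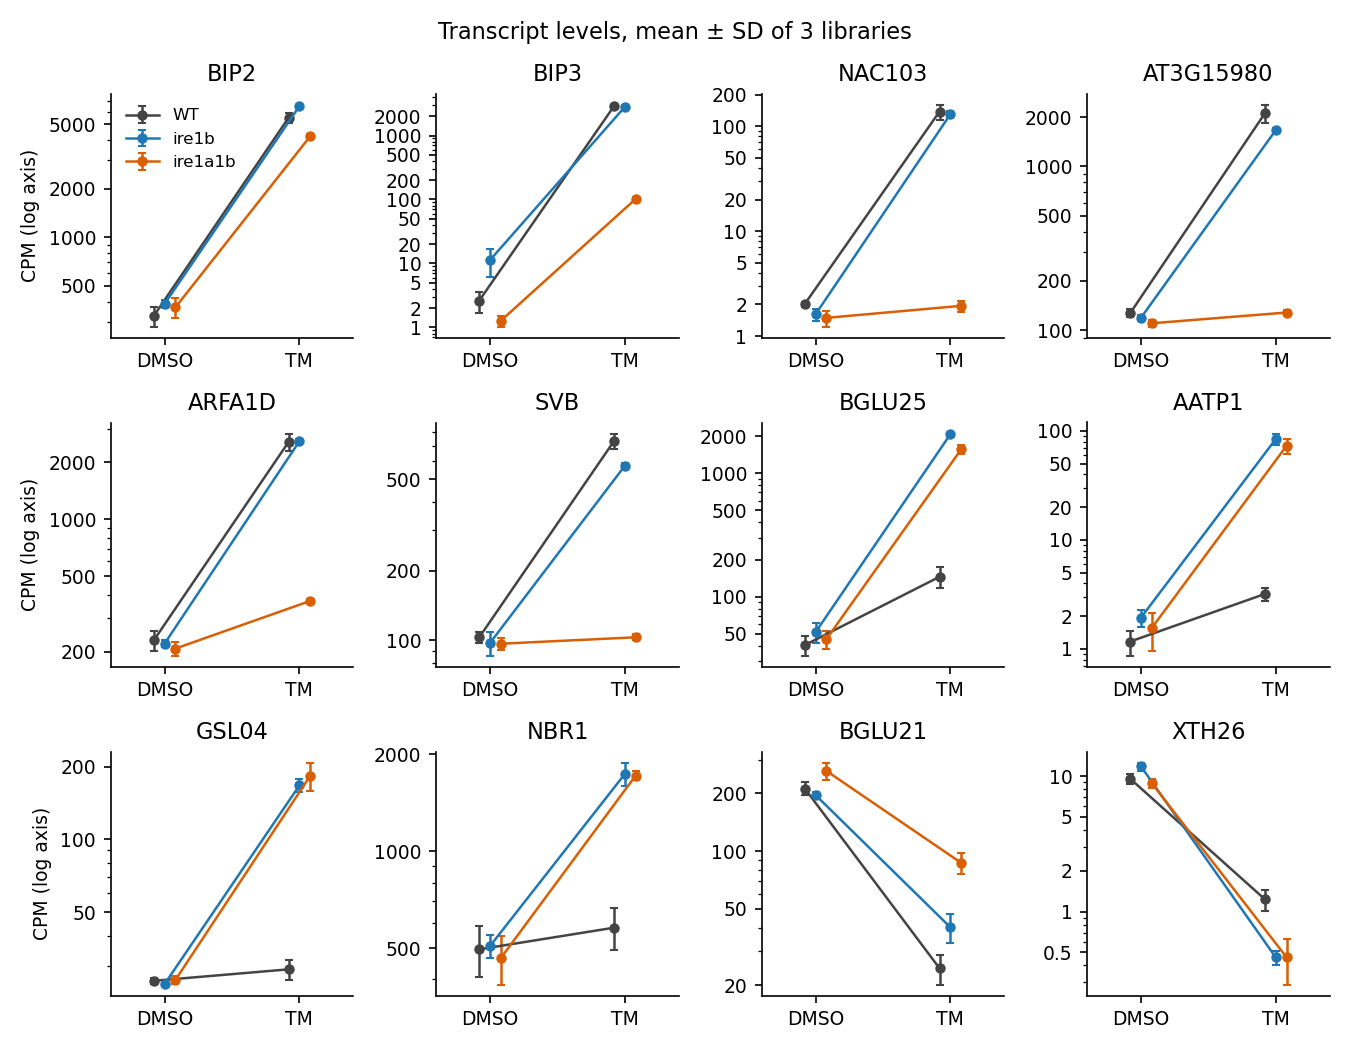
CPM (mean and SD of 3 libraries, log axis) of 12 genes named in the text, by labelled group.

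The libraries labelled ire1a1b were also compared with those labelled ire1b, which differed in IRE1A counts, with no call for IRE1B. NAC103 (62.4-fold, log2 -5.96 ± 0.24, adjusted p = 1.3e-09) and AT3G15980 (12.1-fold, -3.59 ± 0.12, adjusted p = 2.9e-10) again responded less in ire1a1b. So did ARFA1D (6.56-fold, -2.71 ± 0.14, adjusted p = 1.7e-08) and SVB (5.53-fold, -2.47 ± 0.12, adjusted p = 1.3e-08). BIP3 did not pass (-1.63 ± 0.43, adjusted p = 0.15), but passed with DESeq2 (0.008) and without the third ire1b DMSO library (-1.31, adjusted p = 0.047). BZIP60 did not pass (-0.9 ± 0.39, adjusted p = 0.64), but passed without the 4 replicate 1 libraries (-1.12, adjusted p = 0.00011). NBR1 (0.1) and ATG8D (-0.07) did not pass. The response of GAMMA-VPE (AT4G32940), a vacuolar processing protease gene, was 1.6-fold higher in ire1a1b (0.68 ± 0.09, adjusted p = 0.00042). It stood at 87.3 ± 4.15 and 42.3 ± 1.64 CPM in WT, 94.8 ± 4.25 and 71 ± 3.39 in ire1b and 90 ± 4.99 and 108 ± 4.64 in ire1a1b.

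Of the ER lists in this comparison, ER-associated degradation was lower in 7 of 11 (9 over the list alone, median log2 -0.59, camera adjusted p = 1.4e-33, 2.9e-05 with an estimated correlation). ER folding was lower in 6 of 22 (15, median -0.41, 3.7e-28, 0.011 with an estimated correlation). UPR regulators were lower in 3 of 13 (3, median -0.06, 1.4e-10, 0.0077 with an estimated correlation), and genes of ER translocation and N-glycosylation in 2 of 15 (3, median -0.13, 4.7e-08, 0.0077 with an estimated correlation). The Sec61 alpha gene AT1G29310 (-1.14 ± 0.11, adjusted p = 1.9e-05), UBC32 (-1.17 ± 0.09, adjusted p = 2.3e-06) and ERO1 (-1.28 ± 0.2, adjusted p = 0.0035) were examples. Class III peroxidases were higher in 3 of 59 (8, median 0.43, 8.5e-10, 0.016 with an estimated correlation), with AT3G32980 at 0.81 ± 0.15 (adjusted p = 0.013). With an estimated correlation 4 calls were lost. They were cytosolic heat shock (8 of 8 not passing, 1 higher over the list alone, median 1.08, camera adjusted p = 2.6e-05, but adjusted p = 0.31 with an estimated correlation) and salicylate and camalexin defence (14 of 14 not passing, 3, median 0.51, 0.00022, but adjusted p = 0.34 with an estimated correlation). The others were ER body and lectins (1 of 19 higher, 3, median 0.18, 3.1e-05, but adjusted p = 0.34) and hypoxia (11 of 11 not passing, 2, median 0.41, 6e-04, but adjusted p = 0.41, and 0.078 without the first ire1a1b DMSO library). Over all genes 38 responses were higher and 122 lower in ire1a1b, 160 in all (edgeR quasi-likelihood). DESeq2 called 270, a replicate block 316 (622 within each genotype) and a fit without the 4 replicate 1 libraries 254. Of the 122, 75 rose with TM in both labels and 44 rose in ire1b with no call in ire1a1b.

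The last question was how the labels differed in DMSO. Between ire1b and WT 6 genes differed (3 higher, 3 lower, edgeR quasi-likelihood), with 825 at an unadjusted p below 0.05, fewer than the 1031 expected by chance. A count below that number can come from p-values that are too large, so it does not show that the labels are alike. SHL1 (AT4G39100), a chromatin reader gene, was lower in the libraries labelled ire1b (16.4 ± 0.579 against 35.1 ± 5.71 CPM, log2 -1.1 ± 0.12, adjusted p = 0.003, but 0.052 without ire1b DMSO replicate 2). BIP3 was higher (11.3 ± 5.22 against 2.63 ± 0.934 CPM, log2 2.11 ± 0.3, adjusted p = 0.017). Its adjusted p was 0.17 and 0.15 without WT DMSO replicate 1 or 3 and 0.12 and 0.14 without ire1b DMSO replicate 1 or 2. AT5G46295 was higher (2.97 ± 0.39, adjusted p = 0.011, but 0.13 and 0.088 without WT DMSO replicate 1 or 3 and 0.096 without ire1b DMSO replicate 2). The lectin family gene AT5G35940 was lower (-1.78 ± 0.26, adjusted p = 0.017, but 0.13 without WT DMSO replicate 1 and 0.12, 0.16 and 0.18 without ire1b DMSO replicate 1, 2 or 3). The other 2, outside the rule for named genes, were named after the values were seen. AT3G29633 was lower (0.0576 ± 0.0633 against 1.07 ± 0.285 CPM, adjusted p = 0.011, but 0.052 without WT DMSO replicate 3 and 0.077 and 0.14 without ire1b DMSO replicate 1 or 2). AT5G01320 was higher (3.52 ± 0.161 against 1.48 ± 0.159 CPM, adjusted p = 0.011, but 0.13 and 0.078 without WT DMSO replicate 1 or 2 and 0.077 and 0.13 without ire1b DMSO replicate 1 or 2). Without the 4 replicate 1 libraries of WT and ire1a1b the adjusted p of BIP3 was 0.55 and that of AT5G01320 0.058. A fit to these 2 groups alone called none of the 6. The count was 10 with DESeq2, 3 after thinning or without replicate 1 of every group, 2 and 3 without WT DMSO replicate 1 or 3, and 2 and 0 without ire1b DMSO replicate 1 or 2.

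Between the libraries labelled ire1a1b and WT 27 genes differed in DMSO, 22 higher and 5 lower (edgeR quasi-likelihood). A fit to these 2 groups alone called only 1, IRE1A, so every other call named here ended there, and 17 were called without replicate 1 of every group. The higher genes included the reticulon family genes AT1G68230 (13.4 ± 1.16 against 5.45 ± 0.303 CPM, log2 1.3 ± 0.09, adjusted p = 2.7e-06) and AT3G18260 (1.17 ± 0.13, adjusted p = 0.00043). They also included AT4G09950 (1.38 ± 0.12, adjusted p = 2.6e-05), NS2 (AT3G07420, 1.07 ± 0.1, adjusted p = 5.2e-05) and AT1G29520 (0.99 ± 0.06, adjusted p = 1.1e-06). Others were BGLU33 (AT2G32860, 0.97 ± 0.14, adjusted p = 0.0038), c-NAD-MDH3 (AT5G56720, 1.28 ± 0.17, adjusted p = 0.0018) and AT5G46295 (2.39 ± 0.4, adjusted p = 0.022). The adjusted p of AT5G46295 was 0.16, 0.055 and 0.13 without WT DMSO replicate 1, 2 or 3 and 0.12 and 0.095 without ire1a1b DMSO replicate 2 or 3. Besides IRE1A, AT1G18830 was lower (0.0285 ± 0.0248 against 1.18 ± 0.455 CPM, adjusted p = 0.0064, but 0.071 and 0.052 without ire1a1b DMSO replicate 1 or 2). AT5G26270 was lower too (-1.01 ± 0.17, adjusted p = 0.028). Its adjusted p was 0.2 and 0.093 without WT DMSO replicate 1 or 3 and 0.16, 0.089 and 0.19 without ire1a1b DMSO replicate 1, 2 or 3. Outside the rule and named after the values were seen, AT3G29633 (0.0911 ± 0.0382 against 1.07 ± 0.285 CPM, adjusted p = 0.0038) and MRD1 (AT1G53480, 0.0783 ± 0.0903 against 0.809 ± 0.0905 CPM, adjusted p = 0.038) were lower. The adjusted p of MRD1 was 0.098, 0.18 and 0.11 without WT DMSO replicate 1, 2 or 3 and 0.18 and 0.19 without ire1a1b DMSO replicate 1 or 3. Without the 4 replicate 1 libraries of WT and ire1a1b it was 0.22, and that of AT1G18830 was 0.097.

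Between the libraries labelled ire1a1b and ire1b 33 genes differed in DMSO, 28 higher and 5 lower (edgeR quasi-likelihood). A fit to these 2 groups alone called 7, which kept IRE1A, AT1G68230, AT1G29520 and AT4G09950 of the genes named here. The reticulon family gene AT1G68230 (1.17 ± 0.09, adjusted p = 1.2e-05) and AT1G29520 (1.12 ± 0.06, adjusted p = 2.1e-07) were among the higher ones. So were AT4G09950 (1.24 ± 0.12, adjusted p = 9.9e-05), AT1G29380 (0.95 ± 0.11, adjusted p = 0.00061) and SHL1 (0.95 ± 0.12, adjusted p = 0.00095). The lower ones were IRE1A, BIP3 (-3.15 ± 0.33, adjusted p = 0.00025) and AT1G18830 (0.0285 ± 0.0248 against 2.46 ± 1.06 CPM, adjusted p = 0.00025). The others were AT2G04650 (-0.39 ± 0.07, adjusted p = 0.043) and, named after the values were seen, AT2G05915 (0.216 ± 0.116 against 2.02 ± 0.461 CPM, adjusted p = 0.0068). The adjusted p of AT2G04650 was 0.12 with DESeq2, 0.053 with RLE scaling, 0.49, 0.19 and 0.063 without ire1b DMSO replicate 1, 2 or 3 and 0.23, 0.26 and 0.19 without ire1a1b DMSO replicate 1, 2 or 3. It was 0.12 with no filter and 0.34 without the 4 replicate 1 libraries of WT and ire1a1b. That of AT2G05915 was 0.072 and 0.064 without ire1a1b DMSO replicate 1 or 2.

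Among the lists in DMSO, the UPR regulators alone kept a call with an estimated correlation. They were lower in 1 of 13 (1 over the list alone) in ire1a1b against WT (median log2 -0.07, camera adjusted p = 8.4e-14, 0.0079 with an estimated correlation), and likewise in ire1a1b against ire1b (-0.13, 2e-12, 0.013 with an estimated correlation). The 1 gene was IRE1A itself. ER folding had a call in ire1b against WT (1 of 22 higher, 4 over the list alone, median 0.19, 3.3e-12, but adjusted p = 0.49 with an estimated correlation). In ire1a1b against WT 22 of 22 did not pass (median 0.16, 1.7e-05, but adjusted p = 0.5 with an estimated correlation, 0.077 without WT DMSO replicate 1 and 0.24 without ire1a1b DMSO replicate 2). In ire1a1b against ire1b 1 was lower (median -0.04, 0.004, but adjusted p = 0.99 with an estimated correlation, 0.091 without ire1b DMSO replicate 2 and 0.45 and 0.076 without ire1a1b DMSO replicate 1 or 3). Cytosolic heat shock had a median of 0.57 in ire1b against WT (adjusted p = 0.72 with an estimated correlation, 0.74 without WT DMSO replicate 1, 0.089 without ire1b DMSO replicate 3). It had a median of 0.37 in ire1a1b against WT (0.85 with an estimated correlation, 0.78 and 0.23 without ire1a1b DMSO replicate 2 or 3). There it turned down without WT DMSO replicate 1 (0.67). Class III peroxidases had a median of 0.12 in ire1b against WT (0.72 with an estimated correlation, 0.32 without WT DMSO replicate 1, 0.18 without ire1b DMSO replicate 3). Their median was 0.08 in ire1a1b against WT (0.29 with an estimated correlation, 0.27 without WT DMSO replicate 1, 0.1 without ire1a1b DMSO replicate 3). In ire1a1b against WT the root hair markers had a median of 0.19 (adjusted p = 0.21 with an estimated correlation, 0.099 without WT DMSO replicate 1, 0.058 without ire1a1b DMSO replicate 1). There the xyloglucan endotransglucosylase/hydrolases had a median of 0.06 (0.29 with an estimated correlation, 0.22 and 0.07 without WT DMSO replicate 1 or 3, 0.28 and 0.12 without ire1a1b DMSO replicate 1 or 2). Of these XTH10 (AT2G14620) was higher (1.7 ± 0.2, adjusted p = 5e-04). Hypoxia had a median of 0.29 in ire1b against WT (0.72 with an estimated correlation, 0.2 without WT DMSO replicate 1). Its median was -0.31 in ire1a1b against ire1b (0.99 with an estimated correlation, 0.51 without ire1a1b DMSO replicate 1). In ire1a1b against ire1b the genes of ER translocation and N-glycosylation had a median of 0 and a mean of -0.54 (1 of 15 lower, 0.0021, but adjusted p = 0.19 with an estimated correlation). The 1 lower gene was AT1G18830 (log2 -6.08, 0.0285 CPM in ire1a1b), whose near-zero counts weigh on that mean. The endodermis markers had a median of 0.19 (0.036, but adjusted p = 0.8 with an estimated correlation). Their adjusted p was 0.076 with a replicate block, 0.18 without ire1b DMSO replicate 2 and 0.085 and 0.18 without ire1a1b DMSO replicate 2 or 3.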

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

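All tests of explanations in this part were chosen after the results were seen, except the test on genes that fell in WT in a comparison without WT libraries, which was written before. The values of the closing list were set out because the interaction term differed between genotypes.

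The first pattern was a TM response more positive in the libraries of both mutant labels than in WT. There were 436 genes positive in both interactions (19.4 under independence) and 166 negative in both (8). Of the 436, 358 rose in both labels, while in WT 91 rose and 81 fell. Both interactions share the WT libraries, and part of the overlap could come from that: the correlation of the interactions across genes was 0.73, against 0.5 in simulations with shared controls. Replicate 1 libraries standing apart were argued against by 387 of the 436 genes (88.8%) that kept both positive calls without the 4 of them. A weaker TM exposure of WT than of ire1b was argued against, as far as ER genes track it, by the 28 ER folding and degradation members that rose in WT. Their median ire1b against WT difference was 0 (quartiles -0.03 to 0.13), with median TM responses of 3.01 in WT and 3.07 in ire1b. Genes already at their full rise would not show such a difference, and choosing them by their rise in WT lowers it. The test did not cover ire1a1b. Chance low values in the WT libraries were argued against by choosing the genes without 1 WT replicate. The left-out WT pair had a TM change of at most 0.19 in the median, against 1.03 to 1.19 in the mutant labels. The mutant medians came from the fit that chose the genes, which raises them, so part of this gap is built in. Chance high values in the mutant libraries were not tested. A biological difference is a hypothesis that these tests leave standing. Part may still come from the shared controls, from TM exposure or from chance high values in the mutant libraries.

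The second pattern was IRE1B, not lower in the libraries labelled ire1b or ire1a1b. Of the 6 genes called between ire1b and WT in DMSO, 5 had TM libraries that also separated without overlap in the same direction, against 5% by chance. That share takes DMSO and TM libraries as independent, but residuals of equal replicate number correlated by 0.5 to 0.69 in WT and 0.15 to 0.32 in ire1b. Any lasting difference between sets of WT samples could also separate them. The test therefore cannot decide whether the libraries labelled ire1b are WT libraries. That IRE1A reads were counted for IRE1B was argued against by the IRE1B difference between ire1a1b and ire1b of -0.13 (SE 0.11), where IRE1A differed by -2.08. Transcript made from the disrupted gene outside the disrupted part could give the 39.6 CPM in the libraries labelled ire1b. This stays open, since gene totals do not show which part of the gene was read.

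The third pattern was the 228 of 1189 genes that fell with TM in WT and had a positive interaction in ire1a1b against WT (median 0.78). The same genes had medians of 0.43 in ire1b against WT (81 called positive), which choosing them on the WT libraries raises, and 0.3 in ire1a1b against ire1b (17 called positive). Chance low values in the WT TM libraries were argued against, for the part beyond ire1b, in the comparison without WT libraries, where all genes that fell in WT had a median difference of 0.23 (camera adjusted p = 0.00021 with an estimated correlation, 81.7% above 0 against 49.2% of all genes), and for the part shared with ire1b by genes chosen again without 1 WT replicate, whose ire1b response lay above that of the left-out WT pair by medians of 0.25, 0.44 and 0.55 (lower quartiles 0.06, 0.32 and 0.38), the first a share of 0.514 of the 0.49 in its fit, barely past the bound of 0.5. The 14 root hair and endodermis markers did not fall less in ire1a1b, with a median difference of -0.59 (quartiles -0.74 to -0.26) against 0.78. Their transcripts may respond to TM themselves rather than follow the amount of root tissue, so this cannot decide whether less root tissue was lost in ire1a1b. Secretory proteins may make up more of these genes: the odds ratio of an N-terminal hydrophobic segment, against other genes that fell in WT, was 1.83 (95% interval 1.32 to 2.58, 168 of 228 against 580 of 960, Fisher p = 0.00018), but 1.39 over strata of fold change and expression (0.975 to 2), which holds 1 and leaves this open.

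The 22 genes higher in ire1a1b than in WT in DMSO had a median TM response of -0.17 in WT, with 5 that fell and 1 that rose, which did not decide whether they are genes that TM lowers.

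For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split gave 2453, 4639 and 3064 calls for the TM responses in WT, ire1b and ire1a1b, with 1, 1 and 1 split as large (itself), and 6, 27 and 33 in the DMSO comparisons, again 1, 1 and 1, and the highest other split gave 0 in each (edgeR; unadjusted counts of the real splits were 4965, 6755, 5472, 825, 431 and 671, where 1031 are expected by chance). For the interactions chance was not excluded by the share of splits: 11 of 100 were as large as the 855 of ire1b against WT (highest other 1550), 9 of 100 as the 1262 of ire1a1b against WT (highest other 3447) and 7 of 100 as the 160 of ire1a1b against ire1b (highest other 303). All 10 others in the first and all 6 in the last kept the TM libraries of each genotype whole, and splits that mixed them gave at most 1 and 10. A split that keeps them whole also keeps any TM difference between the genotypes. The share over all splits therefore cannot measure chance. In ire1a1b against WT 6 of the 8 others kept them whole, and the 2 that mixed them (3447 and 2236 calls) set the replicate 1 libraries of DMSO against those of TM, a structure of the samples, beside a blocked value of 2341. Of the 7 mixed splits that did so the others gave 874, 706, 4 and 0, and the 86 that did not gave 0. Among its 18 splits that part as many pairs, those that mixed the TM libraries gave 0 (the real split had 3481 genes at an unadjusted p below 0.05, and DESeq2 gave it 1564).

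The TM response differed between ire1b and WT in 855 genes. It was larger in the libraries labelled ire1b by log2 2.57 for GSL04, 1.46 for KOB1, 1.96 for UGT71C2, 2.77 for GSTU18, 1.27 for AT1G48440, 2.15 for GSL11, 1.58 for AT2G24040 and 3.49 for BGLU25. It was lower for AT3G29410 (-2.24), AT4G15390 (-2.68), AMT1;3 (-2.4), AT3G45710 (-1.82), FUT6 (-1.67), tny (-1.6), GH9C1 (-1.18), HIPP25 (-1.36) and BIP3 (-2.15). By median of lists it differed for autophagy (0.06), ER body (-0.29), root hair (-0.59), arabinogalactan and fasciclin-like (0.35) and lipid transfer proteins (0.55), which an estimated correlation did not keep.

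Between ire1a1b and WT it differed in 1262 genes. It was larger in the libraries labelled ire1a1b for GSL04 (2.65), AT1G48440 (1.33), GAMMA-VPE (1.31), GSL11 (2.2), GSL8 (1.44), GSL10 (1.14), UGT71C2 (1.76) and PME1 (1.12), and lower for AT3G15980 (-3.84), NAC103 (-5.73), AT4G32670 (-2.44), SVB (-2.75), AT2G41870 (-1.89), AT1G62020 (-2.09), ARFA1D (-2.64), PDIL2-3 (-1.48) and BIP3 (-3.78). List medians were -0.41 for ER folding, -0.58 for ER-associated degradation, -0.06 for UPR regulators, -0.3 for ER translocation and N-glycosylation, 0.11 for autophagy, 1.8 for cytosolic heat shock, -0.52 for root hair, 0.47 for arabinogalactan and fasciclin-like, 0.38 for class III peroxidases and 0.49 for lipid transfer proteins, of which ER-associated degradation kept its call with an estimated correlation.

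Between ire1a1b and ire1b it differed in 160 genes. It was larger in ire1a1b for GAMMA-VPE (0.68), SGT1A (0.71), AT1G70160 (0.59), AT4G24340 (0.97) and ZIP3 (1.45), and lower for AT3G15980 (-3.59), NAC103 (-5.96), AT4G32670 (-2.1), SVB (-2.47) and AT2G41870 (-1.97). List medians were -0.41 for ER folding, -0.59 for ER-associated degradation, -0.06 for UPR regulators, -0.13 for ER translocation and N-glycosylation, 0.18 for ER body, 0.51 for salicylate and camalexin defence, 1.08 for cytosolic heat shock, 0.41 for hypoxia and 0.43 for class III peroxidases. The first 4 of these and the peroxidases kept their calls with an estimated correlation.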

How the results depend on the processing

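Fits without the 4 replicate 1 libraries of WT and ire1a1b, without replicate 1 of every group or with a block within each genotype, and the left-out libraries for lists and overlap, were added after the data were seen. In the order TM in WT, ire1b and ire1a1b, then interactions ire1b against WT, ire1a1b against WT and ire1a1b against ire1b, the counts of 2453, 4639, 3064, 855, 1262 and 160 were 530, 1446, 987, 399, 506 and 76 with a threshold of log2 1, and 16 each for the DMSO comparisons of ire1a1b with WT (27) and with ire1b (33). With a replicate block they were 4142 (TM in WT), 4844 (ire1a1b), 1567 (ire1b against WT, whose replicates the numbers did not pair), 2341 (ire1a1b against WT) and 316 (ire1a1b against ire1b, not paired either), and the overlap of TM responses went from 919 to 1660. In the other paired comparisons it gave 6491 for TM in ire1b and 36 for ire1a1b against WT in DMSO. In unpaired comparisons the block ended 1 list call (endodermis, ire1a1b against ire1b in DMSO, adjusted p = 0.076) and changed no named gene's call. With a block within each genotype the 6 counts were 5811, 7861, 6337, 2467, 3486 and 622. Fits to the groups of a comparison alone gave 848 for TM in WT, 1567 for ire1a1b and, in DMSO, 0 for ire1b against WT (6 over all libraries, 10 with DESeq2, 825 at an unadjusted p below 0.05, with 1031 expected by chance), 1 for ire1a1b against WT and 7 for ire1a1b against ire1b. DESeq2 gave 270 for ire1a1b against ire1b (99 higher, 171 lower) and 10 for ire1b against WT in DMSO. Thinning gave 3 for the latter. Without the 4 replicate 1 libraries ire1b against WT had 1295 and ire1a1b against ire1b 254, and without replicate 1 of every group the DMSO counts were 3 for ire1b against WT and 17 for ire1a1b against WT. Leaving out 1 library gave 1553 to 2380 for TM in WT (1553 without WT TM replicate 2, 1606 without replicate 3), 3600 to 3811 for ire1b, 2327 to 3025 for ire1a1b, 624 to 830, 981 to 1351 and 114 to 142 for the interactions, and in DMSO 0 to 6 for ire1b against WT (2 and 3 without WT replicate 1 or 3, 2 and 0 without ire1b replicate 1 or 2), 20 to 23 for ire1a1b against WT and 24 to 30 for ire1a1b against ire1b. It gave 68 to 81 list calls (74 with all libraries), 647 to 948 genes in the overlap, -2.06 to -1.94 for IRE1A (ire1a1b against WT), and for IRE1B 0.15 to 0.34 (ire1a1b against WT) and 0.24 to 0.48 (ire1b against WT). Of the 74 list calls 38 held with an estimated correlation and 56 with fry, 66 held without the 4 replicate 1 libraries, 64 without replicate 1 of every group and 73 with a replicate block. In DMSO, cytosolic heat shock in ire1a1b against WT turned to the other direction (-1 for down, adjusted p = 0.67) without WT replicate 1, and hypoxia in ire1a1b against ire1b turned up (1, adjusted p = 1) without replicate 1 of every group. Of 236 results of named genes, 233 held with DESeq2, 235 with RLE scaling, 227 without the 4 replicate 1 libraries and 207 with fits to the groups of a comparison alone (an alternative added for named genes after the data were seen). RLE scaling moved no count by over 1.5 times. Depth limits genes near the filter, and 6801 genes were not tested. The cause of these shifts was not tested.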

Other observations

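The enrichment test and the tests of the hypotheses were chosen after the results were seen, except the test on genes that fell in WT in a comparison without WT libraries. Transcripts that fell with TM coded more often for proteins with an N-terminal hydrophobic segment, as signal peptides and membrane anchors have. In WT 748 of 1188 genes that fell had one (63%), against 17.3% of the other tested genes (odds ratio 8.11, 95% interval 7.16 to 9.2, Fisher p = 5.2e-247). In the libraries labelled ire1b the share was 40.4% (963 of 2386, odds ratio 3.24, 2.95 to 3.55), and in those labelled ire1a1b 40.3% (547 of 1357, odds ratio 2.97, 2.64 to 3.33). Of the genes that rose, 13% had one in WT, 15.3% in ire1b and 19.4% in ire1a1b, against 20% of all 20465 tested genes with a translated protein. Whether these shares differ between genotypes was not tested. The Fisher test and the intervals took genes as independent, though those that fell in WT had an estimated correlation of 0.039. They were also not stratified by expression, so they may be too sharp.

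Further genes had responses larger than in WT. GSTU18 (AT1G10360) stood at 5.13 ± 0.365 and 6.73 ± 0.384 CPM in WT, in DMSO and with TM, and at 3.83 ± 0.382 and 34.4 ± 2.18 in the libraries labelled ire1b (interaction log2 2.77 ± 0.18, adjusted p = 7e-07, edgeR quasi-likelihood). UGT71C2 (AT2G29740), a glucosyltransferase gene, stood at 16 ± 0.549 and 24.1 ± 0.936 in WT, 16.3 ± 0.634 and 95.5 ± 8.45 in ire1b and 14.7 ± 1.04 and 75.3 ± 9.13 in ire1a1b. PME1 (AT1G53840), a pectin methylesterase gene, stood at 77.1 ± 2.85 and 89.6 ± 3.08 in WT and at 73.9 ± 1.74 and 187 ± 11.6 in ire1a1b (interaction 1.12 ± 0.08, adjusted p = 3.7e-07). Among the responses smaller than in WT, the acyltransferase gene AT4G15390 stood at 74.3 ± 16.9 and 16.7 ± 3.67 in ire1a1b, and the fucosyltransferase gene FUT6 (AT1G14080) at 9.45 ± 0.705 and 8.04 ± 0.373 in WT and 10.2 ± 1.37 and 2.74 ± 0.431 in ire1b (interaction -1.67 ± 0.17, adjusted p = 2.6e-05).

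A hypothesis for the falls in WT is decay of transcripts at the ER by the IRE1 ribonuclease, a known activity of IRE1. It predicts weaker falls of secretory transcripts where IRE1 activity is low. IRE1A counts were low in ire1a1b alone, and counts cannot show whether IRE1B was active in either mutant label. Among genes that fell, the odds ratio for the hydrophobic segment was 8.11 in WT, 3.24 in ire1b and 2.97 in ire1a1b. It was thus lower in ire1b as well, which does not single out IRE1A. Whether these values differ between genotypes was not tested. Genes that fell in WT had a median difference of 0.23 in ire1a1b against ire1b. In ire1b against WT it was 0.1, where IRE1A counts were not lower (96.5 against 85.3 CPM) and choosing the genes on the WT libraries raises the value. Among the 1189 that fell in WT, 228 had a positive call in ire1a1b against WT, but 44 had a negative one. XTH26 and AT2G39040, among the largest falls in WT, fell further in ire1a1b. The 228 had medians of 0.3 in ire1a1b against ire1b and 0.43 in ire1b against WT, raised by the same choice. The odds ratio for the hydrophobic segment among those that fell less in ire1a1b was 1.83 (1.32 to 2.58), and 1.39 over strata of fold change and expression, with an interval that holds 1. Lower transcription could give these values as well, since counts after 6 h do not part synthesis from decay. A test would be to block transcription before TM in WT, a single ire1a line and the line labelled ire1a1b, and to compare the decay of BGLU21 and PRXCB with that of a cytosolic transcript.

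A second hypothesis is that NAC103, AT3G15980, ARFA1D and SVB, whose rise was smaller in the libraries labelled ire1a1b than in WT and not called as different in those labelled ire1b (interactions with WT of 0.24, -0.25, 0.07 and -0.28), need IRE1A through spliced BZIP60. The data hold no single ire1a line, and IRE1B counts were not lower in either label (39.6 CPM in the libraries labelled ire1b), so a joint need of IRE1A and IRE1B may give the same values. Measuring spliced BZIP60 from the reads and the TM response of these 4 genes in a single ire1a line would part them.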
